A study of Homo sapiens with 8 samples.

How the data were processed

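Gene expression was measured on 8 Affymetrix human expression arrays, each hybridised with biotin-labelled total RNA from human tonsil B cells. Groups were taken from the sample titles: 3 arrays of naive B cells, 2 of pre-germinal centre (pre-GC) B cells and 3 of dark zone germinal centre B cells. The description field of the pre-GC and dark zone samples names memory B cells instead, so the group names rest on the titles. The labels give no sorting markers, donors or treatment, and they say only that RNA extraction and labelling followed the manufacturer's standard protocol. The series also names blood in its title, and no blood sample was analysed here.

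The deposited values are ratios on a linear scale, from 0.01 to 232.91, in which each probe set was scaled to a reference of its own. The submitters' processing notes name RMA and GCRMA, without versions, and which of them made the values is not given in the sources used here. The reference of the ratios and any filter are not given either. Array medians lay between 0.833 and 0.907. Such ratios keep no signal level, so genes could not be ranked by brightness, no filter on dim genes could be applied, and differences between groups are the only quantity compared. In all, 33.1% of the probe sets had ratios below 1 on all 8 arrays. For arrays, their number limits the precision.

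All values were log2-transformed with no pseudocount and otherwise used as deposited. Of 22283 probe sets, 68 were controls, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 others had none. Symbols were checked through the Entrez ID against the RefSeq genes of GRCh38.p14, where 19059 matched and 0 symbols changed. Sex-linked marker genes were left out. Coordinates were not used, since the array carries no genome build.

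The design written before the data were examined took the probe set with the highest mean for each gene. Because ratios cannot be ranked by brightness, the mean log2 ratio over all probe sets of a gene was used in its place, and the written rule was run as an alternative. Probe sets that do not respond dilute such a mean, so the fold changes of the 4304 genes with more than 1 probe set can be understated. This gave 11939 genes.

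Genes were tested with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) in 1 model over all 8 arrays and 3 groups, with 5 residual and 1.372 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 11939 genes. A gene was called changed at an adjusted p below 0.05 and at least a 2-fold change. Errors given with log2 fold changes are standard errors (SE) from that model, with n = 3 naive, 2 pre-GC and 3 dark zone arrays. The labels do not say whether arrays of a group came from separate donors, so the p-values measure only the spread between these arrays, which may be technical.

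The groups, the test, the thresholds, the rule for named genes, 26 gene lists and most alternatives were fixed before the data were examined. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists, and again with an estimated correlation. Of the list genes, 491 were measured and 81 were not analysed here. The named genes were the 6 largest rises and 6 largest falls among called genes whose groups did not overlap on any array, up to 4 called members of each list with the largest change, and a fixed set of B cell genes. Immunoglobulin and HLA genes have near-identical relatives whose RNA can bind the same probes, and their values are uncertain.

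The scripts were tested on simulated data with 200 changed genes among 11939 and independent noise at each gene's pooled residual SD. For a log2 change of 2, the test recovered 92.0% of 75 genes in pre-GC against naive, 94.1% of 68 in dark zone against pre-GC and 93.8% of 64 in dark zone against naive. The false calls numbered 0, 0 and 1. Simulated arrays were independent, unlike arrays that may be repeats, so these rates test the scripts and need not hold for the data.

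Alternatives covered the probe set rule, normalization between arrays, the variance model, array weights, the replicate number as a block, the thresholds and leaving out each array. Cyclic loess adjusts differences along each probe set's mean over the arrays, which for these ratios is not a signal level. A change under it alone cannot show that a call is unstable. Quantile normalization gives all arrays 1 distribution of values. Over probe sets with 1 gene symbol, the SD of log2 ratios was 0.612 to 0.630 on naive arrays. It was 0.709 and 0.774 on pre-GC and 0.936 to 0.967 on dark zone arrays. Quantile normalization removes such differences, and whether this ended calls was not tested. Averaging arrays that lay close together, and leaving out probe sets below 1 on all arrays, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.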

Results

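Naive B cells, pre-GC B cells and dark zone germinal centre B cells of human tonsil were profiled on 8 arrays. Naive cells have not met antigen, and the dark zone is the part of the germinal centre in which B cells divide and mutate their antibody genes. The 3 groups held 3, 2 and 3 arrays. The first principal component of the 11939 genes carried 74.3% of the variance, and on it the naive arrays lay between -54.7 and -54.46, the pre-GC arrays at -4.231 and 6.774, and the dark zone arrays between 50.77 and 55.68. The second component, with 15.9%, set the pre-GC arrays, at -37.22 and -36.8, apart from the 6 others, at 3.531 to 17.41.

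Some arrays of a group lay much closer together than others. The SD of the log2 difference over probe sets was 0.147 between dark zone replicates 1 and 2, against 0.485 and 0.476 between these and replicate 3. It was 0.143 to 0.205 between naive arrays and 0.371 between the pre-GC arrays. The actin control, measured at both ends of its transcript, had a 3'-to-5' difference relative to naive of 0.52 and 0.52 (log2) on dark zone replicates 1 and 2 and of -0.48 on replicate 3. It was -0.39 and -0.20 on the pre-GC arrays.

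**Figure D1:**
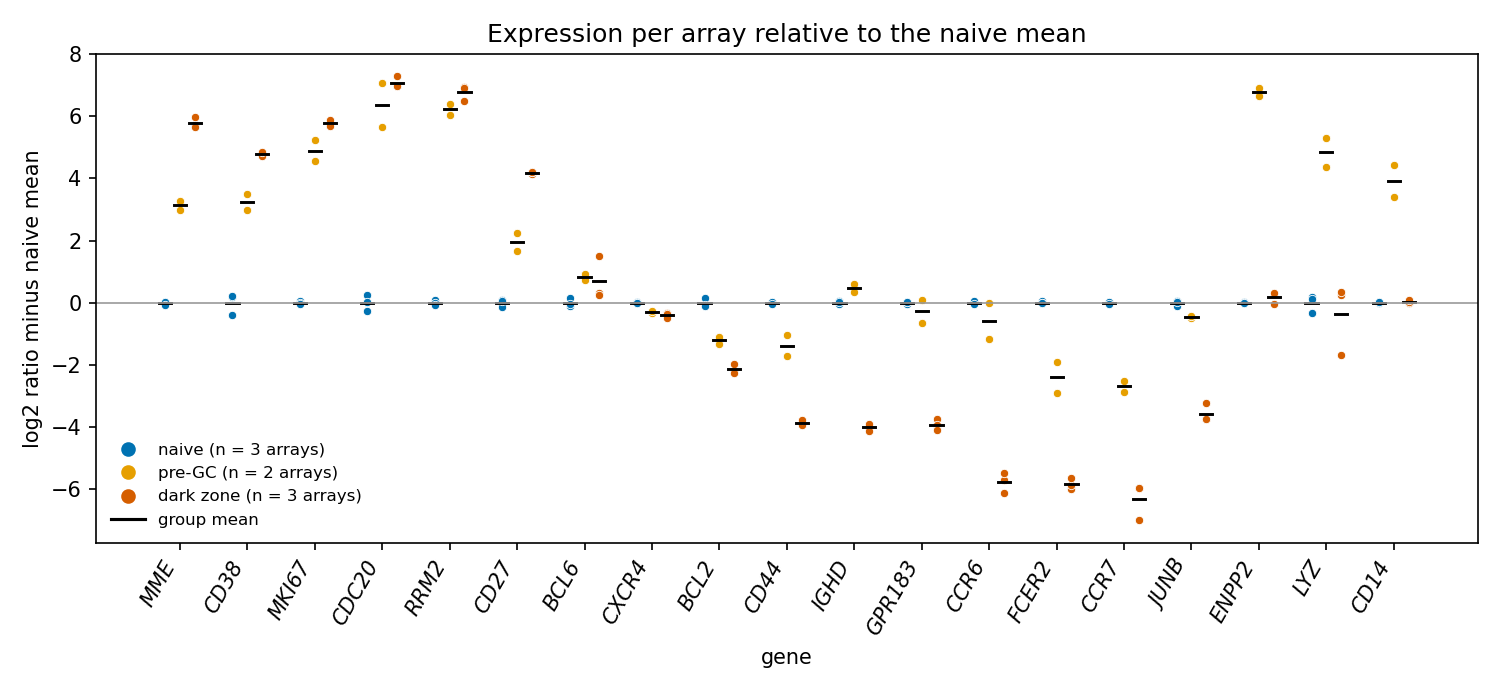
Log2 ratio minus the naive mean (vertical axis) of 19 genes (horizontal axis) on each array; points are arrays of the naive (n = 3), pre-GC (n = 2) and dark zone (n = 3) groups and black lines are group means. MME, CD38 and CD27 were intermediate in pre-GC cells, with means of 3.14, 3.24 and 1.95, while IGHD and GPR183 had means of 0.46 and -0.28 there and of -4.01 and -3.93 in dark zone cells.

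The comparison of pre-GC with naive B cells asked how the cells labelled as preceding the germinal centre differed from resting ones. Many genes of cell division and several germinal centre genes were called higher in pre-GC cells. The mitotic genes CDKN3 and ASPM rose by 6.38 ± 0.24 and 6.32 ± 0.34 (log2 fold change ± SE), and the proliferation marker MKI67 by 4.89 ± 0.18. The germinal centre surface proteins MME (CD10) and CD38 rose by 3.14 ± 0.12 and 3.24 ± 0.22. The lymph node homing receptor CCR7 fell by 2.70 ± 0.32 and the low-affinity IgE receptor FCER2 (CD23) fell by 2.41 ± 0.27. By limma with Benjamini-Hochberg adjustment, 888 of 11939 genes were called changed, 545 higher and 343 lower in pre-GC cells.

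Of 31 measured genes of G2 and mitosis, 30 rose and 0 fell, with a median log2 fold change of 4.31 (camera adjusted p = 2.23e-36, and adjusted p = 0.0735 with an estimated correlation). The count adjusted over the list alone was also 30. The kinesin KIF11 rose by 6.01 ± 0.18, the spindle protein DLGAP5 by 5.99 ± 0.34 and the kinase CDK1 by 5.68 ± 0.16. Of 30 genes of DNA replication and the G1/S transition, 23 rose and 0 fell, and 23 rose when adjusted over the list alone (camera adjusted p = 1.08e-27, and adjusted p = 0.043 with an estimated correlation). The ribonucleotide reductase subunit RRM2 rose by 6.23 ± 0.17, GINS2 by 4.06 ± 0.26 and the replication licensing factor CDC6 by 3.39 ± 0.13. DNA repair and mutation genes rose for 9 of 18 members, with 9 also when adjusted over the list alone (camera adjusted p = 4.55e-07, and 0.043 as the adjusted p with an estimated correlation). Among them, FANCI rose by 3.49 ± 0.28 and BRCA1 by 1.87 ± 0.16.

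Of 19 germinal centre B cell markers, 11 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 6.23e-12, and adjusted p = 0.0582 with an estimated correlation). The transcription factor MYBL1 rose by 5.43 ± 0.27, the signalling regulator RGS13 by 3.71 ± 0.10 and the pro-apoptotic gene BIK by 3.39 ± 0.16. BCL6, the transcription factor required for germinal centres, differed by 0.83 ± 0.37 and was not called (adjusted p = 0.132). The chemokine receptor CXCR4, known for placing cells in the dark zone, differed by -0.29 ± 0.06 and did not reach 2-fold. Of 10 measured dark zone genes, 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.189 with an estimated correlation). This call was lost with quantile normalization (adjusted p = 0.0556), median centring (adjusted p = 0.0665), cyclic loess (adjusted p = 0.313) and without probe sets below 1 on all arrays (adjusted p = 0.0808). The list of memory B cell genes had 6 of 15 higher members and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.000428, and adjusted p = 0.242 with an estimated correlation). The TNF receptor family member CD27 rose by 1.95 ± 0.17 and the DNA sensor AIM2 by 2.05 ± 0.22.

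Of 25 resting and naive B cell genes, 12 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0356, and adjusted p = 0.399 with an estimated correlation). The drug efflux pump ABCB1 fell by 3.98 ± 0.31. The survival gene BCL2, at -1.21 ± 0.13, was not called with the highest-mean probe set (-0.18). The IgD heavy chain gene IGHD differed by 0.46 ± 0.10 and was not called, and its value is uncertain because immunoglobulin genes share probes. The egress-related receptor GPR183 differed by -0.28 ± 0.21 (adjusted p = 0.307), and by 0.09 without pre-GC replicate 2. Immediate early genes, which respond within minutes to stimulation, fell for 5 and rose for 2 of 23 members (camera adjusted p = 0.0335, and adjusted p = 0.366 with an estimated correlation). The counts adjusted over the list alone were 7 and 2. The count of lower members ranged from 0 with close arrays averaged to 14 with quantile normalization, and was 9 without dark zone replicate 3. EGR1 fell by 2.58 ± 0.13 and KLF4 fell by 3.07 ± 0.44, while IER3 rose by 5.56 ± 0.14. The list's call was lost without naive replicate 2 (adjusted p = 0.0597) and without pre-GC replicate 1 (adjusted p = 0.12). Without naive replicate 2 that of the resting list was lost as well (adjusted p = 0.0597), and so it was without dark zone replicate 1 (adjusted p = 0.0521) and with 2 groups in the model (adjusted p = 0.061).

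Plasma cell genes rose for 4 and fell for 1 of 15 members (camera adjusted p = 7.22e-05, and adjusted p = 0.137 with an estimated correlation), and ribosomal protein genes passed as lower with 0 of 28 called (camera adjusted p = 0.00169, and adjusted p = 0.137 with an estimated correlation, but adjusted p = 0.0711 after cyclic loess). Both had the same counts when adjusted over the list alone. Glycolysis genes rose for 5 and fell for 2 of 18 members, the same when adjusted over the list alone (camera adjusted p = 6.87e-06, and adjusted p = 0.137 with an estimated correlation). Oxidative phosphorylation genes rose for 6 of 29 members, with 6 also when adjusted over the list alone (camera adjusted p = 5.54e-20, and adjusted p = 0.043 with an estimated correlation), among them the complex I subunit NDUFS6 by 1.74 ± 0.18 and the ATP synthase subunit ATP5MC3 by 1.45 ± 0.05. Chromatin regulators rose for 8 and fell for 1 of 26, the same when adjusted over the list alone (camera adjusted p = 2.76e-07, and adjusted p = 0.043 with an estimated correlation). The histone chaperone ASF1B rose by 3.68 ± 0.15, the histone methyltransferase EZH2 by 2.84 ± 0.27 and the DNA methyltransferase DNMT1 by 2.27 ± 0.07.

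Of 20 myeloid and dendritic cell markers, 8 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.16e-05, and adjusted p = 0.15 with an estimated correlation). The lysozyme gene LYZ rose by 4.84 ± 0.65, the monocyte receptor CD14 by 3.93 ± 0.26, CST3 by 3.80 ± 0.60 and TYROBP by 3.37 ± 0.30. The sizes differed between pre-GC replicates 1 and 2, at 4.95 and 2.65 for CST3 and 4.45 and 1.59 for C1QA, but 2.79 and 2.78 for CSF1R, with list medians of 0.70 and 0.241. GPNMB, ENPP2 and SELENOP, which are on none of the 26 lists and were the 3 largest rises of any gene, rose by 6.86 ± 0.80, 6.78 ± 0.13 and 6.63 ± 0.65. Without pre-GC replicate 1, GPNMB was 6.05 and SELENOP 5.57, and without replicate 2 they were 7.67 and 7.69. Of 16 follicular dendritic and stromal markers, 4 rose and 0 fell, but the list as a whole did not pass the test (camera adjusted p = 0.364), with a median of -0.084 and a mean of 0.70, and 2 rose without pre-GC replicate 1. The follicle chemokine CXCL13, at 3.66 ± 0.70, lost its call without pre-GC replicate 2 (2.70) and was 4.62 without replicate 1. VCAM1, at 2.61 ± 0.51, lost its call without pre-GC replicate 1 (2.03) and with the replicate block (2.42). T cell markers rose for 0 and fell for 1 of 21 members (camera adjusted p = 0.239), with CD3D lower by a log2 fold change of -1.86 ± 0.25.

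With the 3 naive arrays averaged into 1 sample and dark zone replicates 1 and 2 into another, 90 genes were called in place of 888, and 70.9% of calls were higher with each array centred on its median, in place of 61.4%. Cyclic loess normalization left 51.4% of calls higher and turned the direction of MYBL1, RGS13, MME and EZH2. It ended the list call of the germinal centre markers (adjusted p = 0.926), of DNA repair (adjusted p = 0.0533) and of chromatin regulators (adjusted p = 0.0619). It adjusts along mean ratios, which are not signal levels, so it cannot show whether these calls are stable. It left 7 replication genes called higher in place of 23, 15 genes of G2 and mitosis in place of 30, 2 germinal centre markers in place of 11, 3 DNA repair genes in place of 9 and 2 chromatin regulators in place of 8. With close arrays averaged, these counts were 7, 10, 3, 1 and 2, and 0 resting genes were called lower in place of 12. The higher oxidative phosphorylation genes and myeloid markers then numbered 1 each, and the memory and glycolysis genes 0 each. Averaging leaves fewer samples and the same fold changes for this comparison. With 1 naive sample the spread came from the other groups, so the list calls, which were kept, say little about stability.

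The comparison of dark zone with pre-GC cells asked what further set germinal centre cells apart. The homing receptors CCR6, CCR7 and GPR183 fell by 5.18 ± 0.35, fell by 3.62 ± 0.32 and fell by 3.65 ± 0.21, and IGHD fell by 4.48 ± 0.10. MME rose by 2.65 ± 0.12, CD38 by 1.54 ± 0.22 and CD27 by 2.23 ± 0.17. By limma with Benjamini-Hochberg adjustment, 1073 genes were called, 689 higher and 384 lower in dark zone cells, while 125 of the lower and 74 of the higher ones changed at least 4-fold. The median gene was higher by 0.10 (log2) in dark zone cells, and by 0.0035 after cyclic loess.

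Of 23 immediate early genes, 14 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 3.71e-19, and adjusted p = 0.0261 with an estimated correlation). IER3 fell by 5.43 ± 0.14, the nuclear receptor NR4A2 fell by 3.26 ± 0.44 and the AP-1 subunit JUNB fell by 3.13 ± 0.16. IER3 had risen by 5.56 from naive to pre-GC cells, a course also taken by myeloid markers, while EGR1, JUN and FOSB fell at both steps. Of 24 light zone and activation genes, 6 fell and 0 rose, and 8 fell when adjusted over the list alone (camera adjusted p = 2.6e-10, and adjusted p = 0.0261 with an estimated correlation). FCER2 fell by 3.43 ± 0.27 and the NF-kappaB inhibitor NFKBIA fell by 2.45 ± 0.25. The chemokine gene CCL4 took the course of IER3, at 1.504 from naive to pre-GC cells and then -2.175, while FCER2 fell at both steps. Whether myeloid cells contributed to these falls was not tested. The activation marker CD83 differed by -0.49 ± 0.13 and was not called. Resting and naive B cell genes fell for 14 and rose for 3 of 25 members, the same when adjusted over the list alone (camera adjusted p = 7.52e-13, and adjusted p = 0.0463 with an estimated correlation). Trafficking and adhesion receptors fell for 8 and rose for 1 of 23, with 9 and 1 when adjusted over the list alone (camera adjusted p = 1.08e-05, and adjusted p = 0.03 with an estimated correlation), among them the hyaluronan receptor CD44, which fell by 2.49 ± 0.18.

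Interferon response genes fell for 6 and rose for 1 of 20 members, also when adjusted over the list alone (camera adjusted p = 1.41e-09, and adjusted p = 0.227 with an estimated correlation). IFI44L fell by 4.41 ± 0.07 and XAF1 fell by 2.10 ± 0.16. Glycolysis genes fell for 3 and rose for 0 of 18 members, also when adjusted over the list alone (camera adjusted p = 0.00641, and adjusted p = 0.29 with an estimated correlation), and the list's call was lost without pre-GC replicate 2 (adjusted p = 0.0501). The glucose transporter SLC2A3 fell by 3.37 ± 0.08, while the hexokinase HK2, at -1.31 ± 0.15, was not called with the highest-mean probe set (-0.20). IGHM, which encodes the IgM heavy chain, was at -1.74 ± 0.16 and not called with that probe set (-0.92), with the same doubt about shared probes as IGHD. Plasma cell genes fell for 2 and rose for 1 of 15 (camera adjusted p = 0.00142, and adjusted p = 0.227 with an estimated correlation, but adjusted p = 0.0598 after cyclic loess), and B cell lineage and receptor signalling genes fell for 1 and rose for 1 of 20 (camera adjusted p = 0.00081, and adjusted p = 0.181 with an estimated correlation). Antigen presentation genes passed as lower with 0 of 20 called (camera adjusted p = 5.96e-05, and adjusted p = 0.131 with an estimated correlation). Oxidative phosphorylation genes passed as higher with 0 of 29 called (camera adjusted p = 0.000846, and adjusted p = 0.29 with an estimated correlation), but not under quantile normalization (adjusted p = 0.104). These 4 lists had the same counts when adjusted over the list alone.

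Of 19 germinal centre markers, 10 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00142, and adjusted p = 0.283 with an estimated correlation). SUGCT rose by 2.99 ± 0.34, with 2.33 without pre-GC replicate 1 and 3.64 without replicate 2, ELL3 by 1.75 ± 0.16 and the death receptor gene FAS by 1.73 ± 0.23. BCL6 differed by -0.14 ± 0.37, by 0.50 with the highest-mean probe set and by -0.55 to 0.07 with 1 array left out. CXCR4 differed by -0.11 ± 0.06, and neither was called. The list of 10 measured dark zone genes had 1 higher and 0 lower member, also when adjusted over the list alone, and did not pass the test (camera adjusted p = 0.879). Of 30 replication genes, 9 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 0.000183, and adjusted p = 0.29 with an estimated correlation). MCM10 rose by 1.84 ± 0.13 and the cyclin CCNE2 by 1.80 ± 0.09. Quantile normalization ended this list's call (adjusted p = 0.201), as did cyclic loess (adjusted p = 0.626), and quantile normalization also ended the calls of MCM10 (0.88), CCNE2 (0.99) and ELL3 (0.81). MKI67 differed by 0.89 ± 0.18 and did not reach 2-fold. Of 31 genes of G2 and mitosis, 8 rose, 0 fell and 9 rose when adjusted over the list alone (camera adjusted p = 0.0281, and adjusted p = 0.69 with an estimated correlation).

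The formin FHOD3 rose by 5.59 ± 0.15 and the transcription factor POU4F1 by 3.94 ± 0.15. The neuropeptide gene NMU, at 4.03 ± 1.19, lost its call when any array but dark zone replicate 3 was left out, at 3.32 to 4.15, and was 5.37 without that replicate. The largest falls were those of ENPP2, which fell by 6.60 ± 0.13, the opsin gene OPN3, which fell by 6.33 ± 0.30, SELENOP, which fell by 6.20 ± 0.65 (-5.14 without pre-GC replicate 1 and -7.26 without replicate 2), MMP12, which fell by 6.08 ± 0.06, and the endosomal sorting gene VPS37B, which fell by 6.03 ± 0.07. Myeloid markers fell for 9 and rose for 0 of 20 members, also when adjusted over the list alone (camera adjusted p = 5.31e-10, and adjusted p = 0.0958 with an estimated correlation). LYZ fell by 5.21 ± 0.65 (-4.56 without dark zone replicate 3) and CD14 fell by 3.90 ± 0.26. Follicular dendritic and stromal markers fell for 3 and rose for 0 of 16, also when adjusted over the list alone (camera adjusted p = 0.0142, and adjusted p = 0.271 with an estimated correlation). Their median was 0.019 and their mean -0.60, the call of the list was lost without pre-GC replicate 2 (adjusted p = 0.0615), and 1 fell without naive replicate 3. T cell markers rose for 4 and fell for 0 of 21 members, and the list did not pass the test (camera adjusted p = 0.162). Their count ranged from 0 with close arrays averaged to 5 without dark zone replicate 3. CD3D was at 2.53 ± 0.25 and CD2 at 2.16 ± 0.32. CD3E, at 1.25 ± 0.29, lost its call without pre-GC replicate 1 (1.36) or 2 (1.14) and without dark zone replicate 1 (0.95) or 2 (1.28), and ICOS, at 1.05 ± 0.12, without dark zone replicate 1 (0.94), with median centring (0.97) and with quantile normalization (0.74).

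The balance of the calls depended on the scaling, with 64.2% of them higher as deposited, 37.3% after quantile normalization, which called 612 genes, and 31.5% after cyclic loess, which called 715. With close arrays averaged, 241 genes were called, with all 15 list calls kept. The preset correlation does not depend on the number of arrays, so the kept calls say little about stability. With an estimated correlation, 4 list calls were kept. The call of the G2 and mitosis list was lost with dark zone replicates 1 and 2 averaged (adjusted p = 0.055), without pre-GC replicate 1 (adjusted p = 0.0925), without dark zone replicate 1 (adjusted p = 0.0598) and without dark zone replicate 3 (adjusted p = 0.081), and its direction turned to lower under quantile normalization, where it did not pass (adjusted p = 0.368), and after cyclic loess, where it did (adjusted p = 0.000907). The number of its members called higher, 8, was 4 without pre-GC replicate 1, 18 without pre-GC replicate 2, 1 with close arrays averaged and 0 after quantile normalization or cyclic loess. Replication genes called higher numbered 0 under both normalizations in place of 9, and germinal centre markers 4 under each in place of 10. With close arrays averaged, these 2 counts were 3 and 1. The lower counts were then 5 immediate early, 5 resting, 3 trafficking, 3 myeloid, 2 interferon, 1 glycolysis and 1 light zone and activation genes.

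**Figure D2:**
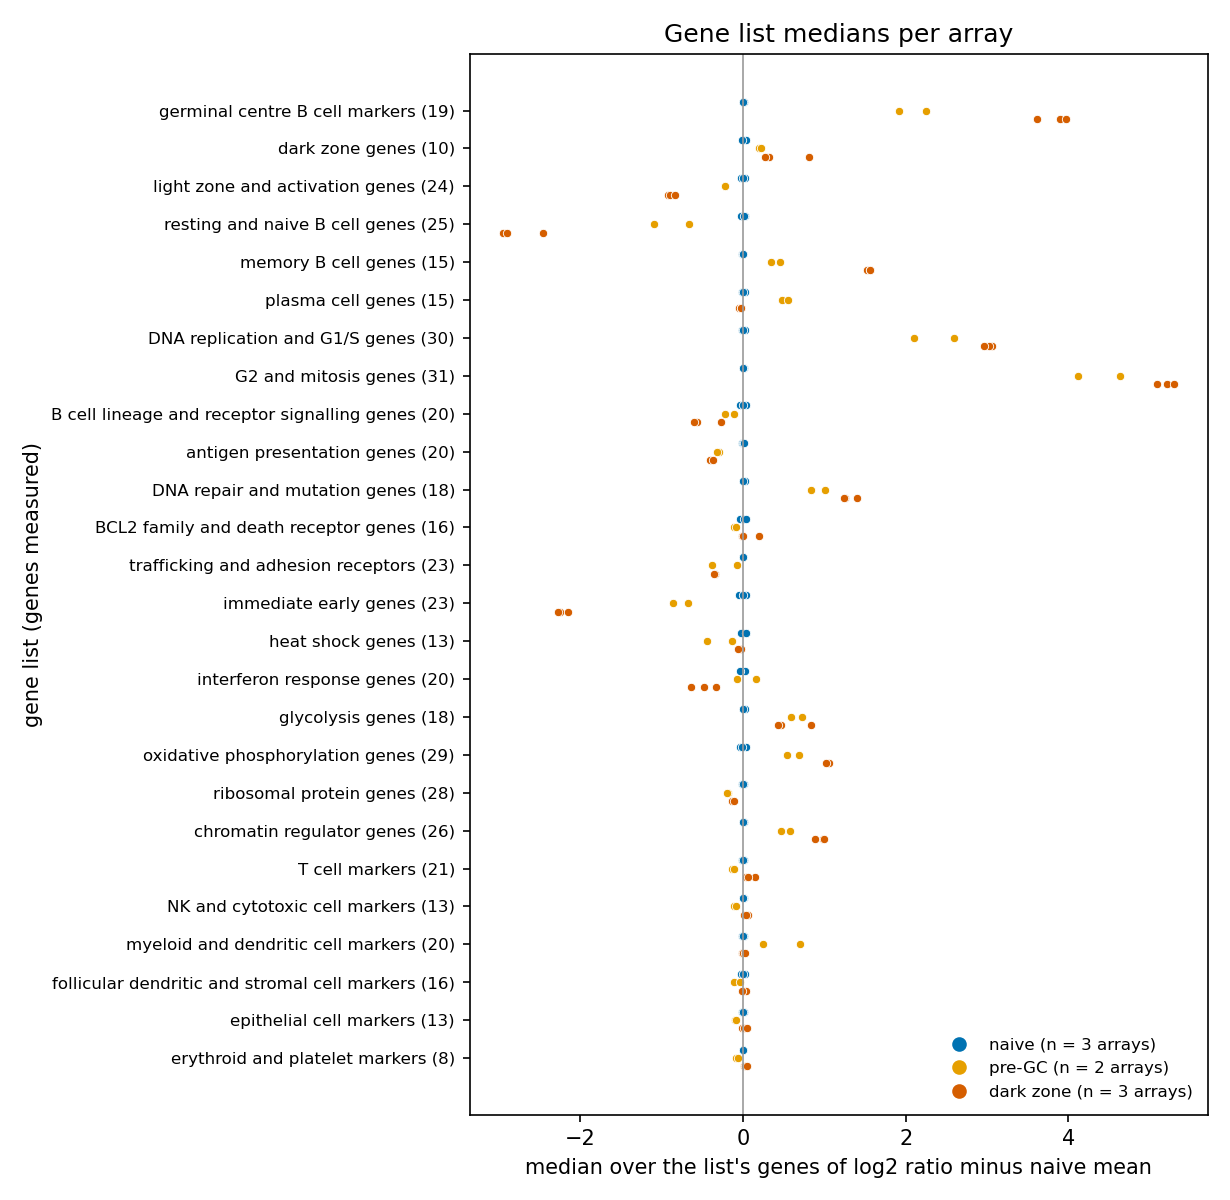
Median over each list's measured genes of the log2 ratio minus the naive mean (horizontal axis) for 26 gene lists (vertical axis, number of genes measured in brackets); each point is 1 array of the naive (n = 3), pre-GC (n = 2) or dark zone (n = 3) group. The medians of G2 and mitosis genes lay at 4.12 and 4.64 on the pre-GC arrays and at 5.09 to 5.30 on the dark zone arrays, and those of immediate early genes at -2.15 to -2.27 on the dark zone arrays.

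The comparison of dark zone with naive cells set against each other the groups that lay furthest apart on the first principal component. CDKN3 rose by 7.24 ± 0.21, KANK1 by 7.01 ± 0.18, MYBL1 by 6.99 ± 0.24 and the growth factor gene PDGFD by 6.92 ± 0.24. VPS37B fell by 8.35 ± 0.06, PLAC8 fell by 6.65 ± 0.20, the cytokine gene IL6 fell by 6.35 ± 0.15 and CCR7 fell by 6.32 ± 0.29. By limma with Benjamini-Hochberg adjustment, 1996 genes were called, 1324 higher and 672 lower. Of all 11939 genes, 53.9% had groups that did not overlap on any array, against 10% by chance for 3 against 3 independent arrays. Close arrays, which may be repeats, separate groups more easily, so this share cannot be read against 10%. In pre-GC against naive cells, where fewer genes were called, it was 76.5% against 20%.

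Germinal centre markers rose for 14 and fell for 0 of 19 members, also when adjusted over the list alone (camera adjusted p = 7.53e-08, and adjusted p = 0.0757 with an estimated correlation). MME rose by 5.79 ± 0.11, SUGCT by 6.04 ± 0.30 and CD38 by 4.78 ± 0.20, while BCL6 differed by 0.69 ± 0.33 (adjusted p = 0.174). S1PR2, a receptor known for holding cells in the germinal centre, differed by 0.04 ± 0.03, and CXCR4 by -0.40 ± 0.05, and neither was called. Of 10 measured dark zone genes, 2 rose and 0 fell, also when adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.326). These were MME and the cyclin CCNB1, at 5.74 ± 0.23. Replication genes rose for 29 of 30 members (camera adjusted p = 3.52e-16, and adjusted p = 0.0757 with an estimated correlation) and G2 and mitosis genes for 30 of 31 (camera adjusted p = 8.36e-19, and adjusted p = 0.116 with an estimated correlation), with the same counts when adjusted over the list alone. MKI67 rose by 5.78 ± 0.16. CD27 rose by 4.18 ± 0.15, and memory B cell genes rose for 8 and fell for 1 of 15 members, also when adjusted over the list alone (camera adjusted p = 0.00287, and adjusted p = 0.3 with an estimated correlation).

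Resting and naive genes fell for 17 and rose for 4 of 25 members (camera adjusted p = 6.92e-08, and adjusted p = 0.0757 with an estimated correlation), the same when adjusted over the list alone. FCER2 fell by 5.84 ± 0.24, CCR6 fell by 5.76 ± 0.31, the quiescence factor KLF2 fell by 5.03 ± 0.28, IGHD fell by 4.01 ± 0.09 and CD44 fell by 3.87 ± 0.16. Immediate early genes fell for 19 and rose for 1 of 23 members, also when adjusted over the list alone (camera adjusted p = 6.28e-11, and adjusted p = 0.0757 with an estimated correlation). NR4A2 fell by 4.75 ± 0.39 and JUN fell by 3.74 ± 0.14. Light zone and activation genes fell for 11 and rose for 2 of 24, and 12 fell when adjusted over the list alone (camera adjusted p = 7.19e-05, and adjusted p = 0.0757 with an estimated correlation), among them NFKBIA, which fell by 2.85 ± 0.22, and CD83, which fell by 1.10 ± 0.12 but was not called without dark zone replicate 3 (-0.96).

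Antigen presentation genes fell for 4 and rose for 0 of 20 members, also when adjusted over the list alone (camera adjusted p = 4.77e-05, and adjusted p = 0.0757 with an estimated correlation), but for 2 without dark zone replicate 1 or with the highest-mean probe set. CIITA, the activator of MHC class II genes, fell by 1.21 ± 0.11, and HLA-DPB1 fell by 1.09 ± 0.10, with probes that related HLA genes can share. Oxidative phosphorylation genes rose for 15 and fell for 0 of 29, the same when adjusted over the list alone (camera adjusted p = 1.03e-12, and adjusted p = 0.0757 with an estimated correlation), among them ATP5MC3 by 1.997 ± 0.049. BIK rose by 4.46 ± 0.15 and FAS by 4.15 ± 0.21, whereas BCL2 was at -2.15 ± 0.11, and at -0.50 and not called with the highest-mean probe set. The plasma cell regulator PRDM1 differed by -0.17 ± 0.13 (adjusted p = 0.382), and the plasma cell receptor gene TNFRSF17 rose by 3.13 ± 0.12. Myeloid markers rose for 0 and fell for 2 of 20 members (camera adjusted p = 0.451).

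As for the lists above, an estimated correlation ended the calls of the other lists that passed. DNA repair genes rose for 10 and fell for 1 of 18 (camera adjusted p = 0.000868, and adjusted p = 0.0757 with an estimated correlation), and chromatin regulators rose for 13 and fell for 1 of 26 (camera adjusted p = 0.00843, and adjusted p = 0.116 with an estimated correlation). Cyclic loess ended both calls (adjusted p = 0.455 and 0.911), with 2 and 4 members higher, and quantile normalization the second (adjusted p = 0.057). With close arrays averaged, 6 DNA repair genes were higher and 4 interferon response genes lower. Trafficking and adhesion receptors fell for 9 and rose for 1 of 23 (camera adjusted p = 0.00445, and adjusted p = 0.0757 with an estimated correlation), and interferon response genes fell for 8 and rose for 2 of 20 (camera adjusted p = 0.00152, and adjusted p = 0.497 with an estimated correlation). Ribosomal protein genes passed as lower with 0 of 28 called (camera adjusted p = 0.000147, and adjusted p = 0.0757 with an estimated correlation). B cell lineage and receptor signalling genes fell for 2 and rose for 2 of 20 (camera adjusted p = 0.0258, and adjusted p = 0.285 with an estimated correlation), with 4 lower without dark zone replicate 3, and their call was lost with the highest-mean probe set (adjusted p = 0.0682) and without probe sets below 1 on all arrays (adjusted p = 0.0703). Adjusted over the list alone, 3 of these fell, and the other 5 lists had the same counts.

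With close arrays averaged, 1161 genes were called in place of 1996, and all 15 list calls were kept. With 1 naive sample and a preset correlation, the kept list calls say little about stability. The members called lower were then 11 of the immediate early genes in place of 19. They were 6 of the light zone and activation genes in place of 11 and 1 of the antigen presentation genes in place of 4. The share of higher calls, 66.3% as deposited, was 53.4% after quantile normalization and 43.9% after cyclic loess, which also ended the list call of the germinal centre markers (adjusted p = 0.14) and turned the direction of MYBL1, RGS13, FANCI, ASF1B, EZH2, DNMT1 and BCL6. Cyclic loess left 9 replication genes called higher in place of 29, 9 genes of G2 and mitosis in place of 30 and 5 germinal centre markers in place of 14.

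Many calls against naive cells were the same in pre-GC and dark zone cells. Of the genes higher in pre-GC cells, 469 were also higher in dark zone cells, where 60.4 would be shared by independent lists, and 218 were lower in both, against 19.3. In opposite directions, 1 gene and 0 genes were shared, against 30.7 and 38.0. In 50 simulated pairs of unchanged groups set against shared naive samples, the share of genes with the same sign was 64.8%, against 64.1% observed, and at most 1 and 0 genes were called by limma in the groups, so the simulation tells nothing about shared calls. The 3 naive arrays are too few to be split, so part of the excess may come from these shared controls. With close arrays averaged, 74 calls were shared in place of 687.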

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

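Of the tests in this part, that of a second macrophage gene list and that of other splits of the arrays were chosen before their results were seen, and the others afterwards.

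Probe sets with no single gene symbol lie outside the comparisons above, and some of them changed. By limma on single probe sets with Benjamini-Hochberg adjustment, 111 of 3129 were called in pre-GC against naive cells, 217 in dark zone against pre-GC and 345 in dark zone against naive. These shares, 3.55%, 6.94% and 11.03%, lay below those of probe sets with 1 symbol, 7.28%, 9.87% and 17.3%.

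Of 20 myeloid markers, 8 were called higher in pre-GC than in naive cells and 9 lower in dark zone than in pre-GC cells. A lower share of B cells could raise the markers of all other cell types alike, or those of some cell types only. T cell markers bear on the first form only. They argue against it, with 0 of 21 called higher and a median of -0.117 (log2) in pre-GC against naive cells. That median was 0.52 below the myeloid one (value 0.522, two-sided permutation p = 0.00048 for the difference of means). The permutation exchanged genes as if independent, and the myeloid list was already seen to rise. Its p-value measures no spread between arrays. Myeloid cells among the pre-GC cells remain open as a hypothesis: a second list of 23 measured macrophage genes, none on the first, left out macrophage genes already seen to rise and had a median log2 fold change of -0.00682, above 98.2% of 10000 random lists. This met the bound set beforehand. That a median near 0 decides little was judged after the value was seen, since 11 members lay above 0 and 12 below. Leaving out genes seen to rise also worked against a high median. Of the members, 2 were called, FOLR2 at 1.27 ± 0.25 and DAB2 at 1.01 ± 0.17, with 1.14 and 0.70 without pre-GC replicate 1. In dark zone against naive cells FOLR2 was at 1.43 and DAB2 at 0.059, so FOLR2 did not follow the pre-GC course of the myeloid markers. MS4A4A, at 1.80 ± 0.95, rested on pre-GC replicate 1, without which it was -0.05. Expression by the B cells themselves was not tested, and the labels name no sorting gate.

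Dark zone replicates 1 and 2 differed with an SD of 0.147, against 0.476 at least for replicate 3. Repeated arrays of 1 RNA sample may be the cause, but the labels do not say, and this cannot be told apart from donors that differ. RNA integrity or labelling cannot be excluded either: the actin 3'-to-5' control differed by 0.997 (log2) between replicates 1 and 2 and replicate 3, while the naive arrays, which may themselves be repeats, spanned 0.00625. The GAPDH control differed less, at 0.153 and 0.121 on replicates 1 and 2 and -0.367 on replicate 3. For actin the pre-GC arrays, at -0.39 and -0.20, also lay away from dark zone replicates 1 and 2, at 0.52 and 0.52. The same limit therefore holds for dark zone against pre-GC cells.

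Immediate early genes were lower in dark zone than in naive cells. All 19 genes called lower were still called lower under each of 3 other scalings (lowest count 19). Median centring moved the median gene only from 0.0162 to 0.0322 (log2), so it could hardly end these calls. Cyclic loess cannot show whether a call is stable. Array scaling is thus argued against by quantile normalization alone, and only for differences that it removes. Handling of the cells before lysis cannot be told apart from a difference between the cell types: the heat shock genes that would bear on it had a median of -0.0234, within the central 95% of random lists, from -0.106 to 0.325. The difference between the cell types themselves remains an untested explanation.

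The 6 naive and dark zone arrays allow 10 splits, too few for a share under 0.05. The real split gave 1996 genes and was the 1 split with as many, and the highest of the others gave 0 by limma, with at most 660 genes at an unadjusted p below 0.05 against 5159. Each other split put naive and dark zone arrays on both sides, so the group difference widened the spread within sides. Low counts there were bound to follow and decide nothing about chance.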

How the results depend on the processing

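The alternatives with averaged arrays and without probe sets below 1 were chosen after the data were seen. Over 305 named results, 5851 of 6402 alternative values had the same direction and side of the threshold, 476 lost the call, 44 gained it and 31 changed sign. The planned filter on low values and the planned floor were not run, because ratios keep no signal level. Signal over background is unknown for the same reason.

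Counts that moved by more than 1.5 times are given for pre-GC against naive, dark zone against pre-GC and dark zone against naive, in this order, from 888, 1073 and 1996. Probe sets tested 1 by 1 gave 1497, 2095 and 3644 (more tests). The adjusted p alone gave 2860, 4044 and 4385, and 1983 shared calls in place of 687. A test against 2-fold gave 254, 185 and 1018, and 215 shared. Averaging close arrays, which leaves fewer samples, gave 90, 241 and 1161, and 74 shared. Quantile normalization gave 612 and cyclic loess 715 for dark zone against pre-GC; for these the cause was not tested. An estimated correlation left 4, 4 and 0 shifted lists of 14, 15 and 15.

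Leaving out each array in turn gave 762 to 1019, 870 to 1348 and 1908 to 2120 genes, 12 to 15, 14 to 15 and 15 to 15 lists, and 575 to 758 shared calls. Where this left 1 pre-GC array, it was assumed to vary like the others. Same-number deviations of naive and dark zone arrays correlated over genes at -0.112, -0.0162 and -0.0542, against -0.0447 to 0.0949 for unlike numbers. Those with pre-GC arrays were 0.012 and -0.00521 (naive) and -0.133 and 0.144 (dark zone). The deviations of 2 arrays from their mean mirror each other, so the pre-GC values cannot show whether samples are paired. The labels name no donors, and the samples were not taken as pairs. The replicate block gave 843, 1074 and 1985 genes and 638 shared calls. The probe set rule written beforehand, the highest mean, gave 982, 1283 and 2247 genes and 763 shared calls. In the main analysis, some called genes with more than 1 probe set had probe sets that pointed in opposite directions. These were 18 of 255, 46 of 339 and 82 of 705 such genes.

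Cyclic loess changed the sign of more named genes than any other setting. The mean along which it adjusts is not a signal level for these ratios, so it cannot show whether a call is stable. Whether it removed real differences was not tested. In pre-GC against naive it gave MYBL1 -0.83, RGS13 -0.14, MME -0.39, EZH2 -0.38, PRKAR2B -0.86, UCHL1 -0.73, KANK1 -0.32 and S1PR2 0.045. In dark zone against pre-GC it gave BIK -0.030 and MKI67 -0.26. In dark zone against naive it gave MYBL1 -0.70, FANCI -0.087, RGS13 -0.51, ASF1B -0.30, EZH2 -0.028, DNMT1 -0.31 and BCL6 -0.53. The other changes of sign, whose cause was not tested, were in pre-GC against naive S1PR2 at 0.023 (quantile) and 0.047 (medians) and PRDM1 at -0.038 (array weights) and -0.0080 (replicate block). With 1 array left out, PRDM1 ranged from -0.15 to 0.20, GPR183 from -0.64 to 0.086, OPN3 from -0.77 to 0.35 and MS4A4A from -0.053 to 3.66. In dark zone against pre-GC, BCL6 was 0.50 with the highest-mean probe set, 0.059 both with dark zone replicates 1 and 2 averaged and with close arrays averaged, and -0.55 to 0.069 with 1 array left out.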

Other observations

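The genes of this and the next paragraph were chosen after their values were seen. Of the genes tested, 147 were higher at both steps, from naive to pre-GC and from pre-GC to dark zone, where independent lists would share 31.45. Besides division genes they included the kinase subunit PRKAR2B, at 3.53 ± 0.36 and then 3.08 ± 0.36 (log2 fold change ± SE), the ubiquitin hydrolase UCHL1, at 3.85 ± 0.34 and 2.06 ± 0.34, and PDGFD, at 4.77 ± 0.27 and 2.15 ± 0.27. The 67 genes lower at both steps, against 11.03 for independent lists, included IL6, at -2.72 ± 0.16 and -3.64 ± 0.16, and the signalling inhibitor SPRY1, at -2.29 ± 0.08 and -1.81 ± 0.08. The values of both steps passed limma's test with Benjamini-Hochberg adjustment, but cyclic loess turned the first step of PRKAR2B to -0.86 and of UCHL1 to -0.73.

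A set of 59 genes was higher in pre-GC than naive cells and lower again in dark zone cells, against 17.53 for independent lists. It held all 8 myeloid markers called higher at the first step, C1QA, C1QB, CD14, CSF1R, CST3, FCER1G, LYZ and TYROBP. Among its other genes were MMP12, at 6.11 ± 0.06 and then -6.08 ± 0.06, the chemokine CXCL2, at 4.56 ± 0.09 and -4.73 ± 0.09, MMP9, at 4.03 ± 0.26 and -4.78 ± 0.26, the cytokine IL1B, at 1.52 ± 0.05 and -1.72 ± 0.05, and the apolipoprotein APOE, at 3.44 ± 0.19 and -3.91 ± 0.19. The reverse course was taken by 33 genes, against 19.79, among them ITM2A, at -3.72 ± 0.27 and 2.14 ± 0.27, and the interleukin 4 receptor gene IL4R, at -1.11 ± 0.14 and 1.56 ± 0.14. The pre-GC values enter both steps with opposite signs, so chance errors in them favour such reversals, and the expected numbers take no account of this.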
